A study of Mus musculus with 6 samples.

How the data were processed

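RNA of CD-1 mouse embryos at embryonic day 13.5 was measured on 6 Illumina whole-genome bead arrays of 1 colour (Cy3), 3 from lower molar tooth germs and 3 from oral tissue without teeth. Per the labels, the replicates are biological, each library pools tissue over several embryos, and libraries of the same number come from the same litter. Titles and descriptions on one side, and source names and tissue fields on the other, assign the tooth germ to opposite sets of 3 libraries. The groups were named by title before the data were examined, and no measured value was used to assign a library.

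The values analysed were the deposited table of log2-scale signals per probe. Per the submitters' processing notes, lumi 2.8.0 was used, and which of its transformations and background corrections was run is not given in the sources used here. The deposited values ran from 6.61 to 14.88, which is a log scale. Whether the scale is a plain log2 or lumi's variance-stabilising transformation, which is close to log2 for bright probes, was not stated. Differences are called log2 differences throughout, and either form may understate the fold of dim genes. The sorted columns of the 6 arrays differed by at most 0.000827, so the table had already been quantile normalized by the authors, and no further normalization was applied. Detection p-values were not used here, so dim probes could not be set against a background. The median of all values was 7.01.

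Probes were named from the platform annotation paired with the table. Of 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 had none in that annotation. Symbols were compared with a RefSeq gene table of the GRCm38.p6 assembly through their Entrez identifiers. 34807 probes matched and 0 symbols changed. No coordinates were used, because no genome build is named for the array. For each gene the probe with the highest mean over the 6 arrays was kept, which left 19057 genes, 9172 of them with several probes. Of 70 genes named by rule, 35 had several probes. For 17 of these the chosen probe was called and another probe was not, and for 0 another probe was called in the opposite direction (limma over all probes).

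The titled groups were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a mean-variance trend, 3 arrays per group and 4 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the 19057 genes, and a gene was called at an adjusted p under 0.05. Errors of differences are the moderated standard errors, and levels are given as mean ± SD over n = 3. The 21 gene lists were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the 21 lists. Camera asks whether a list's members rank differently from all other genes. Alternatives were camera with an estimated correlation, and fry. Counts for each list are given over all genes and adjusted over the list alone.

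Named genes followed a rule fixed before the data were examined. The rule took the 12 genes with the largest difference in each direction among those called with the same sign in all 3 pairs (skipping clone-named and predicted genes), up to 3 members of each list by size among its called members (up to 2 of the smallest p where none was called), and the genes that check the labels, which include Shh, Msx1, Pax9, Lhx8, Bmp4, Myod1, Myog and Acta1. Check genes and list members with no probe of 1 symbol were not analysed here and are not reported.

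Libraries of the same number come from the same litter per the labels. As a check, the correlation of deviations from the group means over the 9528 genes above the median was 0.413, 0.233 and 0.266 for the 3 same-numbered pairs, and between -0.267 and -0.0724 for the other combinations, so the numbers were taken to pair the libraries. The fit without the litter as a block was kept as the main fit, as fixed beforehand, and values with litter as a block (2 residual degrees of freedom) are given where they change the call of a list or of a gene named by rule, or move a list's count of called members by more than 1.5 times, and for both dental lists.

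The alternatives tried were litter as a block or as a random effect, repeated quantile normalization, median centring of each array, removal of dim probes, the mean of all probes of a gene, eBayes without a trend, eBayes with robust shrinkage, array weights, stricter calls, naming the groups by source name, and leaving out each library in turn. Leaving out both libraries of a litter was added after seeing the data. An alternative offset before taking logarithms was planned for a linear table and was not run, because the deposited table is on a log scale.

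The test was checked on simulated data for this comparison, with 200 of 19057 genes changed, all of them drawn from genes above the median gene. At log2 differences of 0.5, 1 and 2 it recovered 64 of 67 (95.5%), 66 of 67 (98.5%) and 66 of 66 (100%) genes, and 14 of 210 calls (6.67%) were false. Of 200 unchanged random lists 3 (1.5%) had a camera p under 0.05 before adjustment, as did 20 of 20 raised lists. Genes were simulated independently of each other. These shares therefore do not cover lists whose members vary together, such as skeletal muscle (estimated correlation 0.709). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.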

Results

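Illumina bead arrays were used to compare gene expression between the lower molar tooth germ and the neighbouring oral tissue of CD-1 mice, an outbred stock, at embryonic day 13.5. At this stage the molar is a bud of thickened oral epithelium surrounded by condensing mesenchyme derived from the neural crest. Each of 3 litters gave 1 tooth germ library and 1 oral tissue library, and tissue of several embryos was pooled for each array. The 6 arrays therefore form 3 pairs, with n = 3 per tissue. Each array carried 45281 probes, of which the brightest per gene was kept for 19057 genes. All 6 libraries had a median signal of 7.01 and an upper quartile of 7.84 on the deposited log scale, which the quantile normalization forces. Pearson's r across all probes lay between 0.995 and 0.997 within a tissue and between 0.988 and 0.993 across tissues. The number of arrays limits the precision of every value below.

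The sample labels contradict each other on which libraries are tooth germ. Titles and descriptions give the tooth germ to one set of 3 libraries, and the source name and tissue fields give it to the other set. The libraries are named here by their titles. If the source name and tissue fields are right, the sign of every difference below turns. The genes chosen to check the labels were therefore examined first, in every library. Msx1, a homeobox gene of dental mesenchyme, had signals of 10.78, 11.41 and 11.09 in the libraries titled oral tissue and 12.67, 12.66 and 12.36 in those titled tooth germ (log2 difference 1.47, SE 0.14, adjusted p = 6.3e-05). Shh, the hedgehog ligand made by dental epithelium, read 7.30, 7.01 and 7.04 in titled oral tissue and 7.62, 7.90 and 8.18 in titled tooth germ, a log2 difference of 0.78 (SE 0.12, adjusted p = 0.0022). The muscle genes went the other way. Myod1 read 9.13, 8.71 and 9.06 against 7.46, 7.52 and 7.50, Myog 9.70, 9.21 and 9.46 against 7.90, 7.95 and 7.91, and Acta1 13.04, 12.27 and 12.90 against 11.13, 10.54 and 10.71, with log2 differences of -1.47, -1.54 and -1.94 and adjusted p-values of 1.6e-05, 1.6e-05 and 7.7e-05. The remaining check genes did not pass the main test. Pax9 read 7.27, 7.59 and 7.47 against 7.64, 7.67 and 7.43 (log2 difference 0.14, adjusted p = 0.476), and Lhx8 read 9.91, 10.31 and 9.81 against 10.30, 10.34 and 10.29 (0.30, adjusted p = 0.204). Bmp4 read 10.71, 11.07 and 10.79 against 11.13, 11.13 and 11.25, a log2 difference of 0.31 with adjusted p = 0.104, and adjusted p = 0.0434 with litter as a block. Without oral tissue library 2 both Lhx8 (0.45, adjusted p = 0.0141) and Bmp4 (0.42, adjusted p = 0.0223) were called, as they were without litter 2 (adjusted p = 0.0379 and 0.0371).

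**Figure D1:**
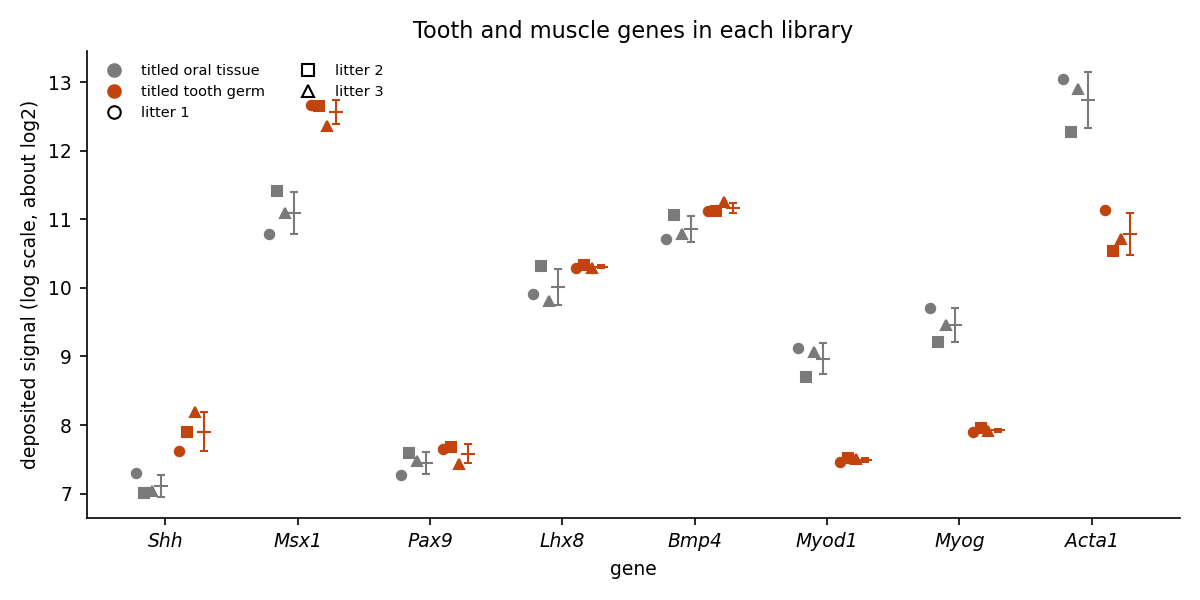
Signal of 8 genes that check the labels, on the deposited log scale (y axis), in each of the 6 libraries; grey points are libraries titled oral tissue, orange points those titled tooth germ, symbols mark the litter, and bars show the mean ± SD of n = 3. Msx1 lies between 12.36 and 12.67 in titled tooth germ and between 10.78 and 11.41 in titled oral tissue, while Myod1, Myog and Acta1 are lower in every library titled tooth germ.

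The comparison of the titled groups asked which genes distinguish the molar tooth germ from oral tissue without teeth. Egr3, Krt17 and Inhba had the largest rise in the libraries titled tooth germ among the genes named by size, and contractile and other muscle genes led those that were lower. Of 19057 genes, 1107 differed (limma, adjusted p under 0.05), 456 of them higher and 651 lower in titled tooth germ. The difference had the same sign in all 3 pairs for each of the 1107 genes. The median size of these differences was 0.44 on the log2 scale, and 125 genes reached a log2 difference of at least 1, of which 31 were higher and 94 lower. With litter as a block 1693 genes were called, 736 higher and 957 lower, among them 1105 of the 1107. Without both libraries of litter 1 the count fell to 549, without those of litter 3 it was 668, and without tooth germ library 2 alone it was 734.

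Among the 12 genes with the largest rise, Egr3, a zinc-finger transcription factor of the immediate-early class, stood at 10.47 ± 0.62 in titled tooth germ and 8.08 ± 0.28 in titled oral tissue (SD, n = 3), a log2 difference of 2.39 (SE 0.24, adjusted p = 1.1e-04) or 5.24-fold. A dimmer Egr3 probe differed by 0.058 and was not called. Krt17, a keratin of ectodermal appendages, stood at 13.81 ± 0.074 against 11.77 ± 0.39, a 4.13-fold difference (log2 2.05, SE 0.15, adjusted p = 1.7e-05). Inhba, which encodes the activin A subunit, was 3.94-fold higher (log2 1.98, SE 0.14, adjusted p = 1.8e-05). The related AP-2 transcription factors Tfap2c and Tfap2b rose by log2 differences of 1.94 and 1.82, and Sp5, a zinc-finger gene that responds to Wnt signals, by 1.95. Foxf1, a forkhead gene that responds to hedgehog signals, had the smallest adjusted p of all genes (6.9e-07) and stood at 9.18 ± 0.050 against 7.45 ± 0.066. Egr2, a relative of Egr3, was higher by 1.77, Msx1 by 1.47 and Cbln1, a secreted organiser of synapses, by 1.33 (log2 differences). The matrix protease gene Mmp9 and Cadps2, a gene of vesicle release, both rose by 1.32, and the call of Mmp9 was lost with robust variance shrinkage (adjusted p = 0.112).

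The 12 genes with the largest fall were mostly muscle genes. Actc1, the cardiac form of sarcomeric actin, which embryonic skeletal muscle also makes, fell by 2.52 on the log2 scale, from 12.53 ± 0.51 in titled oral tissue to 10.02 ± 0.30 in titled tooth germ (SE 0.21, adjusted p = 3.7e-05), and was 5.72-fold higher in titled oral tissue. Mylpf, a fast muscle myosin light chain, fell by 2.05, and Atp2a1, the calcium pump of fast muscle, fell by 1.99. The muscle actin Acta1 and the fast troponin Tnnc2 both fell by 1.94, while the troponins Tnnc1 and Tnnt1 and the actin crosslinker Actn2 had log2 differences of -1.90, -1.82 and -1.89. Tpm2, a tropomyosin, fell by 1.90 at its brightest probe and differed by -0.28 at another bright probe, which was not called. Chrng and Chrna1, subunits of the muscle acetylcholine receptor, had log2 differences of -1.94 and -1.85. Msc, a transcription factor of muscle precursors in the pharyngeal arches, fell by 1.95, from 10.90 ± 0.27 to 8.95 ± 0.047 (adjusted p = 7.5e-06).

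Genes of the tooth bud itself moved up as lists. Of 17 dental epithelium genes on the array 8 rose, 1 fell and 8 were not called, 13 rose and 1 fell when adjusted over the list alone, and 10 rose and 1 fell with litter as a block. The median log2 difference was 0.37, with a camera adjusted p = 8.6e-10 and an adjusted p = 0.0732 with an estimated correlation. Tfap2b led the list, and Sp6, a transcription factor of the enamel organ, rose by 0.89 (SE 0.076, adjusted p = 3.9e-05). Fgf9, an FGF ligand of the dental epithelium, fell by 0.24 (adjusted p = 0.0322). Of 15 dental mesenchyme genes 5 rose and 10 were not called, 9 rose when adjusted over the list alone, and 7 rose with litter as a block (median 0.31, adjusted p = 1.3e-07, and adjusted p = 0.140 with an estimated correlation). These 5 were Inhba, Msx1, and the homeobox genes Dlx2 (1.21, SE 0.18, adjusted p = 0.0013), Dlx1 (0.82, adjusted p = 8.1e-04) and Lhx6 (0.51, adjusted p = 0.0404).

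Genes of surface epithelium at large rose as well. Of 17 such genes 9 rose, 1 fell and 7 were not called, with the same counts when adjusted over the list alone (median 0.43, adjusted p = 1.4e-07, and adjusted p = 0.138 with an estimated correlation). Besides Krt17, Trp63, the master transcription factor of stratified epithelium, stood at 11.39 ± 0.15 against 10.39 ± 0.022 (log2 1.01, SE 0.087, adjusted p = 4.1e-05). The simple-epithelium keratin Krt8 rose by 0.79 (adjusted p = 0.0114), a call lost in 5 of 18 alternatives. Krt15, a keratin of basal cells, fell by 0.39 (adjusted p = 0.0464). Among the 13 members above the upper quartile of all values, the median difference was 0.45. The 95% interval lay below this median for 3 of them, at -0.61 to -0.17 for Krt15, -0.20 to 0.33 for Col17a1, a hemidesmosome collagen, and -0.11 to 0.30 for the cell adhesion gene Cdh1. It lay above this median for Trp63 (0.82 to 1.20) and Krt17 (1.72 to 2.37). The median of the dental epithelium list minus that of the epithelium list was -0.061. This difference did not pass a two-sided permutation test that shuffled genes between the lists, with 100000 resamples (p = 0.857). The test treats genes as independent, though deviations of the epithelium members correlated at 0.183 on average, and it does not measure the spread between litters. Neither this test nor the intervals were among the tests fixed beforehand.

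Of the signalling lists, the FGF list and the BMP and activin list passed the test, and the Wnt and hedgehog lists did not. Among 14 FGF genes 5 rose, 2 fell and 7 were not called, and 6 rose and 3 fell when adjusted over the list alone (median 0.12, adjusted p = 0.0093, and adjusted p = 0.140 with an estimated correlation). With probes of low signal removed the FGF list did not pass (median 0.20, adjusted p = 0.0551). Etv4, a transcriptional target of FGF, rose by 0.96 (SE 0.11, adjusted p = 2.8e-04) and Dusp6, a feedback inhibitor of ERK, by 0.71 (SE 0.079, adjusted p = 2.2e-04), as did Etv5 (0.42), Fgfr2 (0.36) and Fgf8 (0.20). The ligand Fgf10 fell by 0.59 (adjusted p = 0.0296), a call lost in 8 of 18 alternatives, and Fgf9 fell as given above. Of 18 BMP and activin genes 4 rose, 1 fell and 13 were not called, and 5 rose and 1 fell when adjusted over the list alone (median 0.095, adjusted p = 0.0017, and adjusted p = 0.138 with an estimated correlation). Inhba led, followed by the activin antagonist Fst (0.73) and Bmper, an extracellular modulator of BMP (0.73, SE 0.094, adjusted p = 5.9e-04), and by the BMP antagonist Grem1 (0.37). Inhba is also in the dental mesenchyme list and Fst in the dental epithelium list, so these lists are not independent. The BMP antagonist Chrd fell by 0.77 (SE 0.11, adjusted p = 0.0015).

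Among 23 Wnt genes 2 rose, 1 fell and 20 were not called, and 2 rose and 3 fell when adjusted over the list alone; with litter as a block 3 rose and 3 fell. The list's median was 0.027 (adjusted p = 0.679). Sostdc1, an inhibitor of both Wnt and BMP, stood at 11.50 ± 0.13 against 10.57 ± 0.12 (log2 0.94, SE 0.091, adjusted p = 8.2e-05). Lef1, a transcription factor of the Wnt pathway, rose by 0.39 (adjusted p = 0.0483), and Rspo2, which potentiates Wnt signals, fell by 0.36 (adjusted p = 0.0327). Those calls were lost in 10 and 8 of 18 alternatives. Of 10 hedgehog genes 3 rose, 1 fell and 6 were not called, with the same counts when adjusted over the list alone (median 0.11, adjusted p = 0.121). Shh rose together with Gli3 (0.43, adjusted p = 0.0153, lost in 6 of 18 alternatives), a transcription factor of the pathway, and its receptor Ptch1 (0.41, adjusted p = 0.0295). Cdon, a co-receptor that is also made by muscle precursors, fell by 1.00 (SE 0.11, adjusted p = 2.2e-04).

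Transcription factors that mark distal and lingual positions in the mandible moved both ways. Of 12 genes 3 rose, 3 fell and 6 were not called, and 3 rose and 4 fell when adjusted over the list alone. The median was -0.061 and the mean 0.052, while the test pointed down (adjusted p = 0.803). Foxf1 rose by 1.74, and Nkx2-3, a homeobox gene of the oral and pharyngeal floor, by 1.08 (SE 0.094, adjusted p = 4.1e-05), with Foxf2 at 0.15. Alx4, a homeobox gene of craniofacial mesenchyme, fell by 0.84 (SE 0.14, adjusted p = 0.0029, lost in 1 of 18 alternatives), with Osr1 at -0.63 and Tbx3 at -0.38.

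Skeletal muscle genes formed the list with the largest shift. Of 21 members 18 fell and 3 were not called, with the same counts when adjusted over the list alone. The median was -1.56, or 2.96-fold higher in titled oral tissue (adjusted p = 5.9e-37, and adjusted p = 0.138 with an estimated correlation, which was 0.709 for these genes). Within the titled oral tissue group, library 2 deviated from the group mean by -0.30 over these genes, against 0.25 and 0.053 for libraries 1 and 3. Tendon and connective tissue genes were lower too. Of 13 members 7 fell and 6 were not called, and 9 fell when adjusted over the list alone (median -0.50, adjusted p = 1.4e-07, and adjusted p = 0.0845 with an estimated correlation). The matrix genes Dpt, Kera and Col14a1 had log2 differences of -1.30, -1.28 and -0.97 (SE 0.12, 0.14 and 0.090; adjusted p = 6.7e-05, 2.4e-04 and 5.5e-05).

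The lists of neuronal, endothelial and immune cell genes also shifted down in the libraries titled tooth germ, but most neuronal and endothelial members were not called. The list of Schwann cells and glia did not pass. Of 11 neuronal genes 3 fell and 8 were not called, 7 fell when adjusted over the list alone, and 6 fell with litter as a block (median -0.35, adjusted p = 2.5e-06, and adjusted p = 0.138 with an estimated correlation). Oral tissue library 1 stood apart, with a median deviation from the group mean of 0.37 over these genes, against -0.17 and 0.0084 in libraries 2 and 3, and the list medians in the 3 pairs were -0.75, -0.071 and -0.26. The motor and sensory neuron factor Isl1 fell by 1.45 (SE 0.27, adjusted p = 0.0073, lost in 2 of 18 alternatives), the neurofilament gene Nefm fell by 1.19 (adjusted p = 4.3e-04) and the axon growth gene Gap43 fell by 1.10 (adjusted p = 4.9e-04). Of 7 genes of Schwann cells and glia only Sox10, a neural crest and glial factor, was called, and it fell by 1.19 (SE 0.17, adjusted p = 0.0012), as it did when adjusted over the list alone (median -0.0027, adjusted p = 0.592). In this list 4 members had a mean below the median of all values. Of 11 genes of macrophages and leukocytes 7 fell and 4 were not called, and 8 fell when adjusted over the list alone (median -0.31, adjusted p = 1.9e-07, and adjusted p = 0.140 with an estimated correlation). The complement gene C1qc fell by 0.62, the leukocyte membrane gene Laptm5 fell by 0.58 and the mannose receptor Mrc1 fell by 0.55, and the last call was lost in 10 of 18 alternatives. Of 14 endothelial genes 1 fell and 13 were not called, and 3 fell when adjusted over the list alone as well as with litter as a block (median -0.17, adjusted p = 6.0e-04, and adjusted p = 0.230 with an estimated correlation). That gene was Tek, an endothelial receptor kinase, at -0.33 (adjusted p = 0.0268, lost in 8 of 18 alternatives). None of 8 erythroid genes was called by limma in either adjustment, and 0 had an unadjusted p under 0.05 (median -0.021, adjusted p = 0.680), and Slc4a1, the red cell anion exchanger, and Epb42, a protein of the red cell membrane, differed by -0.16 and 0.034 (unadjusted p = 0.361 and 0.382, limma).

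**Figure D2:**
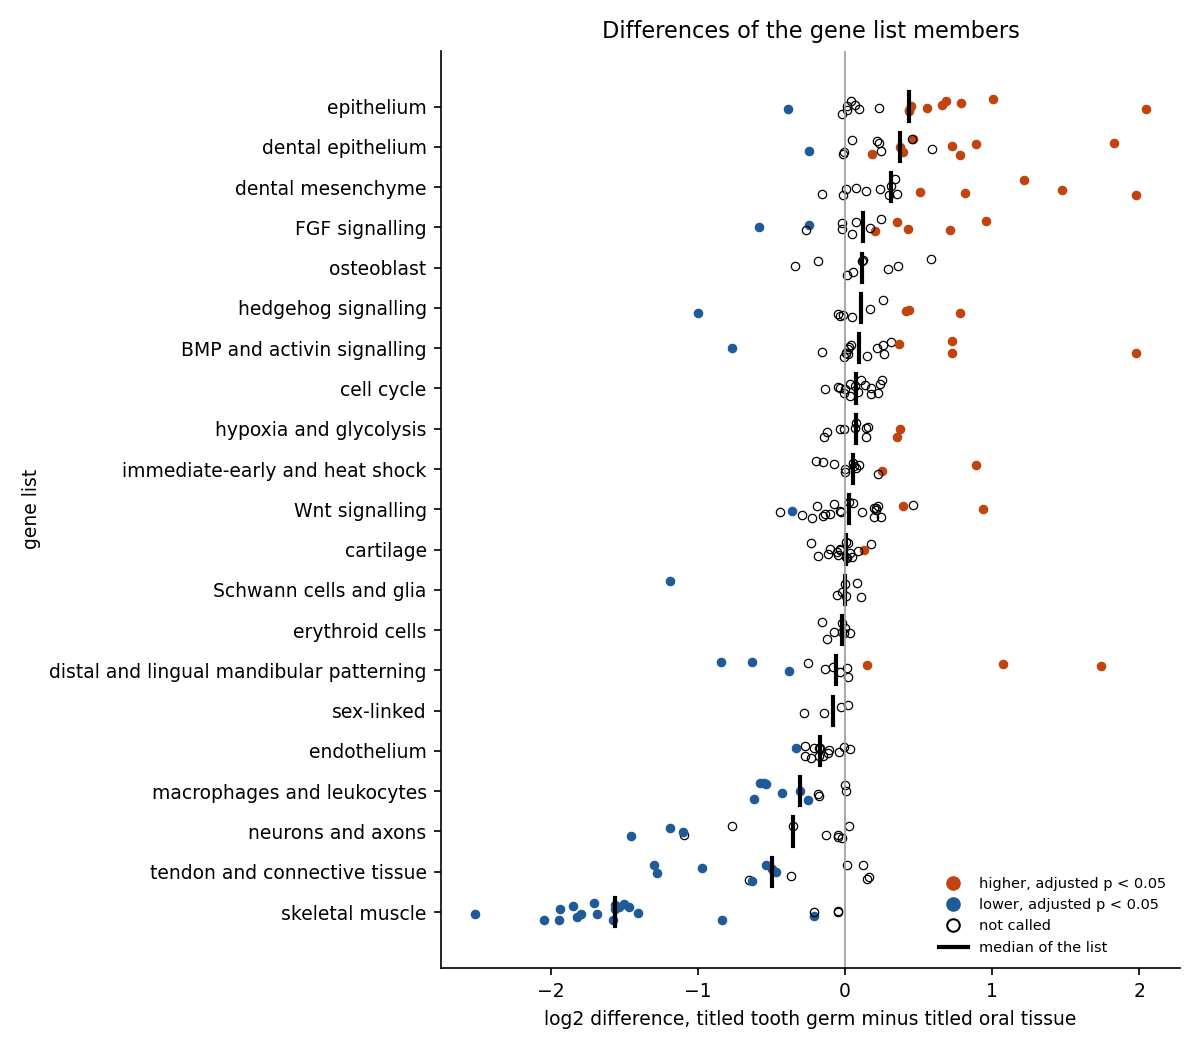
Log2 difference, titled tooth germ minus titled oral tissue (x axis), of each member of the 21 gene lists (y axis, ordered by the list's median); filled points passed limma's test at an adjusted p under 0.05 (orange higher, blue lower), open points did not, and black bars are list medians. Skeletal muscle lies farthest to the left (median -1.56), and the epithelium and dental lists farthest to the right (medians 0.43, 0.37 and 0.31).

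The cartilage and osteoblast lists did not pass the main test. Of 17 cartilage genes 1 rose and 16 were not called, with the same counts when adjusted over the list alone. The median was 0.0063 and the mean -0.017, and the test pointed down (adjusted p = 0.732). Of the 17 members 6 had a mean below the median of all values, where a difference may be understated. Matn3, a cartilage matrix gene of low signal, rose by 0.13 (adjusted p = 0.0223), a call lost in 9 of 18 alternatives. None of 9 osteoblast genes was called by limma in either adjustment, and 3 had an unadjusted p under 0.05 (median 0.12, adjusted p = 0.121). Their list medians in the 3 pairs were 0.48, -0.36 and 0.13. Alpl, the bone alkaline phosphatase, differed by 0.58 (SE 0.23, unadjusted p = 0.0250 by limma, adjusted p = 0.197), and Mmp13, a collagenase, by 0.29 (SE 0.090, unadjusted p = 0.0079, adjusted p = 0.0982), which was called with litter as a block (adjusted p = 0.0353). Alpl was called without oral tissue library 2 (0.91, adjusted p = 0.0024), Mmp13 without tooth germ library 2 (0.42, adjusted p = 0.0019), and both without litter 2. This list depended on single libraries. Its median was 0.30 without oral tissue library 2 (adjusted p = 0.0039), 0.27 without tooth germ library 2 (adjusted p = 0.0017) and 0.43 without both (adjusted p = 8.3e-08), and over all alternatives its adjusted p ran from 8.3e-08 to 0.838.

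**Figure D3:**
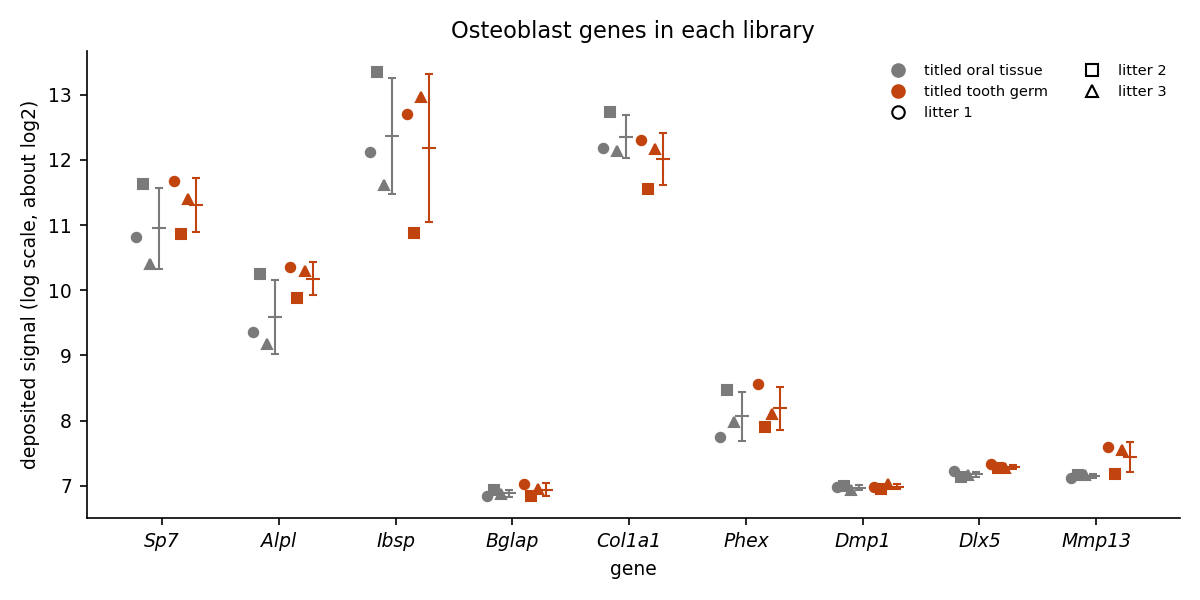
Signal of the 9 osteoblast genes on the deposited log scale (y axis) in each library; grey points are libraries titled oral tissue, orange points those titled tooth germ, symbols mark the litter, and bars show the mean ± SD of n = 3. Ibsp ranges from 11.62 to 13.35 in titled oral tissue and from 10.88 to 12.96 in titled tooth germ, with litter 2 highest in the former and lowest in the latter.

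The lists on the state of the tissue did not pass the main test, and some of them passed under alternatives. None of 16 cell cycle genes was called by limma in either adjustment, and 4 had an unadjusted p under 0.05 (median 0.077, adjusted p = 0.0773). Mcm6 and Mcm7, parts of the replicative helicase, differed by 0.25 and 0.24 (unadjusted p = 0.0221 and 0.0233, limma). Other bright Mcm6 probes differed by -0.031 and 0.21, and neither was called. Mcm6 was called without tooth germ library 3 (0.35, adjusted p = 0.0273) and Mcm7 with the mean of all probes (0.25, adjusted p = 0.0449). The cell cycle list passed without a variance trend (adjusted p = 0.0411), with array weights (0.0313), without oral tissue library 1 (median 0.068, adjusted p = 0.0352) and without tooth germ library 3 (median 0.075, adjusted p = 0.0298), and over all alternatives its adjusted p ran from 0.0298 to 0.230. Of 12 immediate-early and heat shock genes 2 rose and 10 were not called, with the same counts when adjusted over the list alone (median 0.056, adjusted p = 0.159), and the list passed without litter 3 (median 0.068, adjusted p = 0.0394). Egr1, a relative of Egr2 and Egr3, rose by 0.89 (SE 0.15, adjusted p = 0.0042) and Junb by 0.25 (adjusted p = 0.0435). The call of Egr1 was lost without litter 1 (0.76, adjusted p = 0.0759) and without litter 2 (0.72, adjusted p = 0.0544), and that of Junb in 11 of 18 alternatives. Fos differed by 0.062, Jun by -0.20 and the heat shock gene Hspa1a by 0.092, and none of them was called. Of 11 hypoxia and glycolysis genes 2 rose and 9 were not called, with the same counts when adjusted over the list alone (median 0.075, adjusted p = 0.156). These were the glucose transporter Slc2a1 (0.37, adjusted p = 0.0286) and the lactate dehydrogenase Ldha (0.35, adjusted p = 0.0131), with calls lost in 7 and 5 of 18 alternatives. None of 4 sex-linked genes was called by limma in either adjustment, and 0 had an unadjusted p under 0.05 (median -0.084, adjusted p = 0.617), with Xist, made from the inactive X chromosome, at -0.28 and the Y-linked Kdm5d at -0.14 (unadjusted p = 0.377 and 0.179, limma).

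In all 10 lists that passed, the median had the same sign in all 3 pairs. None of the 10 passed with an estimated correlation. The estimate was 0.018 for dental epithelium, 0.012 for BMP and activin and 0.022 for FGF, all near the preset 0.01. Members that vary together therefore do not account for the loss in these lists. Hedgehog, with an estimate of -0.0085, also moved from a camera adjusted p of 0.121 to 0.239. With litter as a block each of the 10 passed, and 13 lists passed fry, which asks whether a list's members move on balance one way without comparing them with other genes. Besides these 10 they were distal and lingual patterning (fry adjusted p = 0.0119), cell cycle (0.0371) and hypoxia and glycolysis (0.0372). The direction fry gave was not recorded, and members of the patterning list moved both ways. Of 70 genes named by rule 59 were called, and 44 of these 59 were called under all 18 alternatives that gave gene values. All 59 had the same sign in all 3 pairs, which the rule required of those named by size. Fgf9, Dlx1, Lhx6, Krt15, Col17a1, Cdh1, Etv5, Fgfr2, Fgf8, Fst, Grem1, Ptch1, Foxf2, Osr1, Tbx3, Fos, Jun, Hspa1a and Ibsp fell outside the naming rule and were chosen after their values were seen.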

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

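Probes outside the gene test also carried a difference between the titled groups. Of 10396 probes without a single gene symbol here, 163 (1.57%) were called by limma at an adjusted p under 0.05 over these probes, 71 higher and 92 lower in the libraries titled tooth germ. They were singled out because they lie outside the comparison of named genes. The 3 probes that share the smallest adjusted p (2.0e-05) differed by 0.59, -1.83 and -1.61 on the log2 scale. No explanation was tested for them.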

How the results depend on the processing

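The alternatives that leave out both libraries of a litter were chosen after seeing the data, and the others before the data were examined. No gene called in the main comparison changed sign in any alternative that kept the titles, and naming the groups by source name and tissue turns the 456 higher and 651 lower genes into 651 higher and 456 lower. Several alternatives could not turn a sign. Litter as a block or random effect and other variance shrinkage leave the differences themselves unchanged. Leaving out a whole litter cannot turn one either, since all 3 pairs had the same sign for each called gene. Litter as a block, which pairs the libraries, raised the calls from 1107 to 1693 (736 higher), made Bmp4 and Mmp13 pass, moved the counts of called members within lists, of which the report gives those that moved by more than 1.5 times and those of both dental lists, and changed no other call of a whole list or of a gene named by rule. Litter as a random effect gave 1430 calls, no variance trend 1042, robust shrinkage 1163, array weights 1218, the mean of all probes 933 and removal of dim probes 1164 of 12162 genes, and repeated quantile normalization or median centring moved nothing, since the arrays already share their quantiles. A log2 difference of at least 1 left 125 genes and an adjusted p under 0.01 left 601. Leaving out libraries, which also leaves fewer arrays, gave 549 to 1025 calls, 195 to 368 higher and 354 to 663 lower; higher calls numbered 284 without oral tissue library 1, 298 without oral tissue library 3, 282 without tooth germ library 2, 268 without litter 2 and 258 without litter 3, and lower calls 410 without litter 3. With an estimated correlation, 10 lists no longer passed at unchanged medians: dental epithelium (0.37), dental mesenchyme (0.31), BMP and activin (0.095), FGF (0.12), epithelium (0.43), skeletal muscle (-1.56), tendon (-0.50), endothelium (-0.17), neurons (-0.35) and macrophages (-0.31). FGF signalling also failed with dim probes removed (0.20), where fewer members were tested. Cell cycle passed without a variance trend (0.077) and with array weights (0.075), Wnt signalling turned with the mean of all probes (-0.026), and the test of distal and lingual patterning turned with robust shrinkage (-0.061) and array weights (-0.048). With libraries left out, list medians ran from -0.038 to 0.029 for cartilage, -0.087 to -0.037 for distal and lingual patterning, 0.055 to 0.12 for cell cycle, 0.019 to 0.43 for osteoblast, -0.024 to 0.080 for Wnt signalling, -0.16 to 0.033 for erythroid cells and 0.025 to 0.068 for immediate-early and heat shock genes. The test changed direction for cartilage without oral tissue library 1, tooth germ library 2 or litter 2, for patterning without oral tissue library 1 or tooth germ library 3, for Wnt signalling without oral tissue library 3, and for erythroid cells without oral tissue library 3, tooth germ libraries 1 or 2, or litter 2. Erythroid cells passed without tooth germ library 3 (-0.16, adjusted p = 0.0489, range 0.0489 to 0.989), and the immediate-early list passed without litter 3 (0.068, adjusted p = 0.0394, range 0.0394 to 0.437). Of single genes that were not called, Epb42 ran from -0.011 to 0.065, Slc4a1 from -0.36 to 0.020 and Xist from -0.54 to 0.085, and they changed sign without oral tissue library 1 (Epb42), tooth germ library 1 (Slc4a1 and Xist) or oral tissue library 3 (Xist). The causes of these changes were not tested. No list that passed was lost when libraries were left out, and 15 of 59 called named genes were lost in at least 1 of 18 alternatives. Without detection p-values, signal over background limits the dim genes; 32 of the 1107 called genes had a mean below the median of all values.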

Other observations

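All families and tests in this part were chosen after the results were seen. Gene families were formed by symbol stem from genes above the median of all values, with at least 5 such members, which gave 377 families. The counts below are of these brighter members only, and camera set them against all genes, dim ones included. Some members are also in the gene lists above, among them Dlx1, Dlx2, Tbx1, Krt17 and Mcm2 to Mcm7, so families and lists are not independent. Of the 377 families 12 passed camera at an adjusted p under 0.05 and none with an estimated correlation (adjusted p = 0.877 for each of these 12). Dlx genes, the homeobox genes that pattern the jaw and teeth, had the smallest p. Of 6 genes under that stem, 1 of them an antisense gene, 3 rose and none fell (median 0.51, adjusted p = 8.7e-04), with Dlx2 at 1.21 and Dlx1 at 0.82, while Dlx3, Dlx5 and Dlx6 differed by 0.59, 0.12 and 0.066 and were not called. With litter as a block Dlx3 was called (adjusted p = 0.00996, against 0.0705 without it). T-box genes went the other way. Of 8 members 3 fell (median -0.19, adjusted p = 0.0146), led by Tbx15, a factor of skeletal and connective tissue mesenchyme, at -0.81 (SE 0.070), while Tbx1, a gene of dental epithelium, differed by 0.45 and was not called. Of 26 keratins 9 rose and 3 fell (median 0.059, adjusted p = 0.0398). Those that rose included Krt6b at 0.57, and those that fell were Krt1 at -0.25, Krt10 at -0.37, both keratins of differentiated epidermis, and Krt15 at -0.39.

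Of 6 genes under the stem Igf 3 fell (median -0.18, adjusted p = 0.0398). These were the growth factor Igf1 at -0.86 (SE 0.094), the receptor Igf2r at -0.84 (SE 0.11) and Igf2bp1, an RNA-binding protein gene, at -0.34, while the ligand Igf2, the receptor Igf1r and Igf2bp3 differed by 0.036, -0.021 and -0.0071 and were not called. Of 8 Abca lipid transporters 4 fell (median -0.17, adjusted p = 0.0066), with Abca3 and Abca8a both at -0.62. Of 5 small heat shock genes 3 fell and 1 rose (median -0.68, adjusted p = 0.0398). Hspb3, a muscle form, stood at -1.09, Hspb1 at -0.83 and Hspb2 at -0.68, and Hspb8 rose by 0.55. The stems Mcm, which holds genes of the replicative helicase and others, and Srsf, of splicing factors, passed as families without a single call by limma. The 8 Mcm genes had a median of 0.20 (adjusted p = 0.0246) and the 10 Srsf genes a median of 0.18 (adjusted p = 0.0398). Mcm2 to Mcm7 are shared with the cell cycle list, which did not pass camera (adjusted p = 0.0773).

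A set of genes followed the litter. A limma test of litter, with tissue in the model, called 130 genes, and 17 of them differed by more than 1 on the log2 scale between the highest and the lowest litter mean. Cops8, a subunit of the COP9 signalosome, read 10.42, 10.60 and 7.19 in the 3 oral tissue libraries and 10.56, 10.47 and 7.32 in the 3 tooth germ libraries, and its tissue difference was 0.047. Csrp1 was lower in litter 3 (litter means 10.12, 10.14 and 8.57), Msmo1, an enzyme of cholesterol synthesis, was higher in litter 2 (8.96, 10.52 and 9.18), and Tmem14c was higher in litter 3 (10.31, 10.24 and 11.98). Xist, which is sex-linked, had litter means of 8.87, 9.58 and 10.03, and the sex makeup of the embryo pools was not tested. Of the 130 genes, 13 were also called between the titled groups. They included the muscle genes Myh8, Myl1, Mylpf, Acta1, Tnnc1 and Csrp3, each with its lowest litter mean in litter 2 (Mylpf 12.03, 11.29 and 11.84). The erythroid genes Hba-x and Alas2 also followed the litter. Whether the tissue makeup of the pools differed between litters was not tested.

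A variant of this outbred stock under 1 probe was tested as the source of all of these differences. For 27 of the 130 genes 38 other bright probes could be set against the brightest one, and 25 of them followed the litter means with a slope of at least 0.5, which argues against that source for the whole set. Among the 25 were probes of Xist, of the muscle genes Csrp3, Myh8, Myl1 and Mylpf, and of other genes such as Creld2 and Zc3h14. The median slope was 0.75, consistent with RNA levels that differ between litters for genes such as Xist (slopes 0.98, 1.28 and 0.72) and Tax1bp3 (0.94). A probe variant stays open for genes whose other probe did not follow, such as Slc25a3 (-0.075) and Trim59 (-0.16), or followed weakly, such as Tmem14c (0.38 and 0.22), and for genes with a single probe, such as Cops8. Pairing the libraries in any of the other ways called at most 14 genes, but a processing batch shared by a litter cannot be told apart from the litter, because no batch that crosses the litters is named.

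The conflict between label fields was weighed with the dental and muscle lists. If the titles were the wrong way round, dental genes would be lower and muscle genes higher in the libraries titled tooth germ. The 32 dental members had a median difference of 0.33, with pair medians of 0.37, 0.19 and 0.43, and the muscle members had pair medians of -1.80, -1.37 and -1.56, which argues against titles that are the wrong way round. A single wrong title is argued against by 0 libraries lying on the other group's side in the dental minus muscle level, which was -2.01, -1.29 and -1.71 in titled oral tissue and 0.34, 0.54 and 0.45 in titled tooth germ. That the source name and tissue fields are the ones in error is therefore a candidate explanation, found and tested on the same values, and no library was regrouped by it.

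Osteoblast genes varied between libraries of one tissue in a mirrored way. Their mean deviation from the group mean was -0.12, 0.35 and -0.23 in the 3 oral tissue libraries and 0.22, -0.35 and 0.13 in the 3 tooth germ libraries, and Ibsp, a bone matrix gene, read 13.35 and 10.88 in the libraries of litter 2. A stage difference between litters was the only biological explanation tested, and it stays open as the whole source. It was tested in 2 ways, both chosen after the pattern was seen. By sign, 0 of 3 pairs deviated the same way, which would count against it. By size, the tooth germ minus oral tissue gap in deviation, averaged over the 9 members, was 0.3444 in litter 1 (95% interval over the 3 litters together 0.054 to 0.63), -0.71 in litter 2 (-1.43 to 0.021) and 0.36 in litter 3 (-0.14 to 0.86), so only litter 1 would count against it. These intervals are over genes, and with 1 library per tissue and litter the spread between libraries is not known, so neither test was taken to decide. Overall array quality or normalization stays open too. The members' median residual SD was 0.355, above the 95th percentile of 10000 lists matched on mean expression, but 15 of the 20 other lists also reached that percentile, so this spread decides nothing. The members' deviations correlated at 0.555 on average, at percentile 100 of the matched lists, and forming jaw bone that was dissected along in varying amounts may be the source. Members of other lists also deviated together, with mean correlations of 0.709 for skeletal muscle, 0.485 for erythroid cells and 0.381 for macrophages (percentiles 100, 99.93 and 99.94). The Wnt, dental mesenchyme, epithelium, endothelium, neuron and cartilage lists lay above the 95th percentile too (96.79 to 99.96). A high percentile alone therefore does not point to bone. The muscle genes deviated by 0.25, -0.30 and 0.053 in the 3 oral tissue libraries and by 0.11, -0.11 and -0.0081 in the 3 tooth germ libraries.

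The 6 libraries can be split into 3 and 3 in 10 ways, so the share of splits as large as the real one cannot be under 0.1. The real split called 1107 genes and was the only 1 to reach that count, and the highest of the other splits called 0 by limma (793 at an unadjusted p under 0.05, against 3262 in the real split). Of the 4 splits that part every litter, the highest of the others had 509 genes at an unadjusted p under 0.05.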
